A study of Mus musculus with 7 samples.

How the data were processed

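Poly(A) RNA of sorted germinal centre B cells from mouse spleen was sequenced from strand-specific libraries, 3 from WT and 4 from Asns_KO mice, all taken on day 9 after immunisation, per the labels. Per the submitters' processing notes the tools were HISAT2 2.1.0 and Salmon 1.4.0 and the genome build was mm10. The notes give no order or role for these tools. Per the file headers, the deposited table of each library holds, for 116546 transcripts, an estimated count of reads, the abundance in TPM that the authors' quantification derived from it, the transcript length and the effective length. Salmon shares reads that match several transcripts between them by a statistical model, so estimated counts of isoforms and of near-identical genes carry an error that the tables do not give. TPM were read but entered no test. The transcript set and annotation release behind the deposited tables are not given in the sources used here.

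Transcripts were joined to genes by identifier with the GENCODE M21 annotation of GRCm38 (the mm10 assembly), from which coordinates, gene types and exons were taken. With their version number 115785 transcripts matched, 192 more matched without it, and 569 did not match and were left out, holding 0.089% to 0.0927% of the counts of a library. Estimated counts were summed to 35498 genes and rounded to whole numbers, and 18203 genes had a count in at least 1 library. The total per library ranged from 52947184 to 64503516. At this depth the median standard error of a log2 fold change was 0.0759. Between-replicate variation, with a common biological coefficient of variation of 9.58%, set the precision of abundant genes. Every pair of libraries of 1 group differed by more than sampling noise, with a chi-square per gene between 18 and 40.5 over genes with more than 200 counts, so each library was counted as 1 replicate.

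Differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, two-sided, genotype as the only term, TMM normalization, filterByExpr with its minimum count of 10), with Benjamini-Hochberg adjustment over the 12197 genes that passed the filter and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are counts per 1000000 of the TMM-scaled library total, and values per transcript are relative to all estimated counts of the library. An exact permutation test over all 35 splits of 7 libraries into 3 and 4 was used for single values, two-sided, and its smallest p is 0.0286.

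Before the data were examined, 36 gene lists were written from general knowledge of B cells and amino acid metabolism, and the 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Every camera adjusted p in the text comes from this limma test unless an estimated correlation is named. The score of a list in a library is the mean over its members of log2 CPM centred on the mean of all 7 libraries.

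The genes named in the text follow a rule also fixed before the data were examined. It takes Asns and Cd79a, then up to 12 protein-coding genes per direction, without immunoglobulin and T cell receptor segments, that passed the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, and up to 4 members per described list with the smallest p. Adk alone met the second part besides the first pair of genes. Genes named outside this rule are said to be chosen after their values were seen.

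The edgeR and camera steps were tested on simulated data with the means, spread and library sizes of these libraries over the same 12197 genes, with 200 changed genes in each of 5 simulations. For the comparison of Asns_KO with WT, 41.2% of genes changed 1.25-fold, 65.1% of genes changed 1.5-fold and 80.6% of genes changed 2-fold were recovered, with a mean of 9.6 unchanged genes called per simulation. The plasma cell list, shifted by 0.3 on the log2 scale, was called in 5 of 5 simulations. Simulated genes were drawn independently, whereas the members of that list had an estimated correlation of 0.268 in the real libraries. The simulations therefore do not show how camera behaves with correlated members. Over all simulations 1 other list was called, while splits of the real libraries other than by genotype called a median of 7. With few changed genes the adjusted threshold is stricter, so the shares of genes recovered are upper estimates here.

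Alternatives changed 1 choice at a time, except the replicate block: the size factors of DESeq2 1.42.0, no filter, the replicate number as a block (which also takes Asns_KO replicate 4, alone in its block, out of the contrast), an offset for effective length, no immunoglobulin genes, DESeq2, limma-voom with quality weights, stricter thresholds, camera with an estimated correlation, fry, another prior count, and leaving out each library in turn. The labels give no sequencing or library batch, so none was examined. The loss of the floxed exons was not examined because the tables hold no values per exon.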

Results

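RNA was measured in germinal centre B cells, the B cells that multiply and mutate their antibody genes in lymphoid follicles during an immune response. The cells were sorted from mouse spleen as CD19-positive, GL-7-positive and CD38-negative cells on day 9 after immunisation with sheep red blood cells. There were 3 wild-type libraries (WT) and 4 libraries from mice carrying a floxed Asns allele together with a cre recombinase expressed from the B cell gene Cd79a (Asns_KO). Asns encodes asparagine synthetase, the enzyme that makes asparagine from aspartate and glutamine. Total estimated counts ranged from 52947184 to 64503516 per library, and 15027 to 15399 genes had a count in each. The design text counts mice, and each library was taken as 1 mouse; the labels do not tie libraries to animals, so p-values describe the spread between these libraries. The labels do not say whether the WT mice carried the cre. Cd79a RNA, from the locus that carries the cre, lay at 513 to 536 CPM in Asns_KO and 1070 to 1130 CPM in WT. These values argue against the same cre dose in both genotypes. The comparison asks what loss of Asns in B cells does to the RNA of germinal centre B cells.

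Asns RNA was low in each of the 4 Asns_KO libraries, at 2.91, 2.31, 3.38 and 3.88 counts per 1000000 counts (CPM), against 27.3, 13 and 19 CPM in the 3 WT libraries. The group means were 3.12 CPM ± 0.67 (SD, n = 4) and 19.8 CPM ± 7.15 (SD, n = 3), a log2 fold change of -2.66 (SE 0.25, 95% interval -3.22 to -2.10; adjusted p = 0.00644, edgeR quasi-likelihood test; exact permutation p = 0.0286, two-sided, the smallest that 3 against 4 libraries allow). Asns lies on the minus strand of chromosome 6 at 7675169 to 7693254 (GRCm38), and nearly all of its counts lay on the 12-exon coding transcript Asns-201. Without Asns_KO replicate 3 the log2 fold change was -2.70 with an edgeR adjusted p of 0.0598.

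Only 2 other genes passed the test, so 3 of 12197 genes differed between the genotypes, 2 lower and 1 higher in Asns_KO. Cd79a, which encodes the Ig-alpha signalling chain of the B cell receptor and whose locus carries the cre, fell from 1100 CPM ± 31.1 (SD, n = 3) to 524 CPM ± 10.2 (SD, n = 4), a log2 fold change of -1.07 (SE 0.03; adjusted p = 1.29e-06, edgeR). It lies on the plus strand of chromosome 7 at 24897381 to 24902197. Adk, which encodes adenosine kinase, the enzyme that turns adenosine into AMP, rose from 44.3 CPM ± 2.47 (SD, n = 3) to 67.3 CPM ± 1.97 (SD, n = 4), a log2 fold change of 0.60 (SE 0.05; adjusted p = 0.00326, edgeR). Each of the 3 genes had no overlap between the groups.

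**Figure D1:**
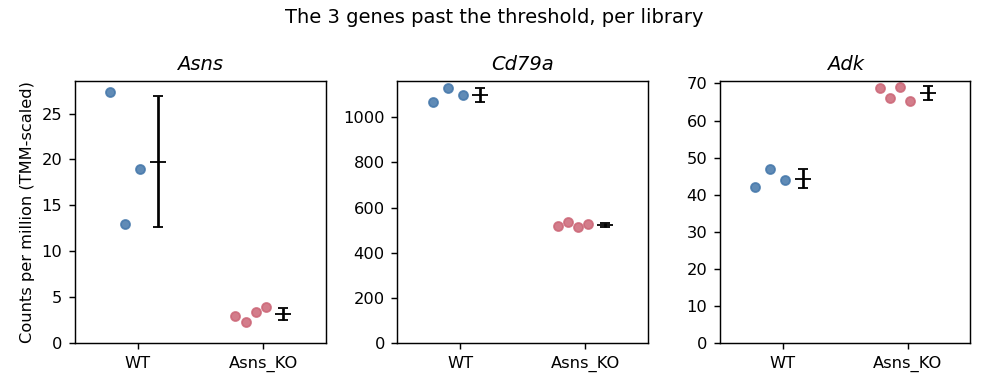
Each panel shows 1 gene past the threshold, with TMM-scaled CPM on the vertical axis (starting at 0), 1 point per library and the mean ± SD beside the points. Asns_KO libraries lie between 2.31 and 3.88 CPM for Asns and between 513 and 536 CPM for Cd79a, below all WT libraries, and above all WT libraries for Adk.

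By the deposited estimates, the gain of Adk lay on 1 of its coding transcripts. Adk spans 21052574 to 21448569 on the plus strand of chromosome 14. The transcript Adk-207, whose first exon lies at 21076152 to 21076321, stood at 28.3 CPM ± 2.83 (SD, n = 3) in WT and 49.3 CPM ± 2.01 (SD, n = 4) in Asns_KO (exact permutation p = 0.0286, two-sided). The transcript Adk-201, with its first exon at 21052574 to 21052700, stood at 15.8 CPM ± 1.20 in WT and 17.2 CPM ± 0.934 in Asns_KO (SD, n = 3 and n = 4; exact permutation p = 0.143). Both transcripts share most of their length, so their split rests on the estimate of the deposited quantification, and these values do not separate a change of isoform from a sequence variant between strains or an effect of mapping. With an offset for effective transcript length the log2 fold change of Adk was 0.76 and its adjusted p rose to 0.215 in edgeR.

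**Figure D2:**
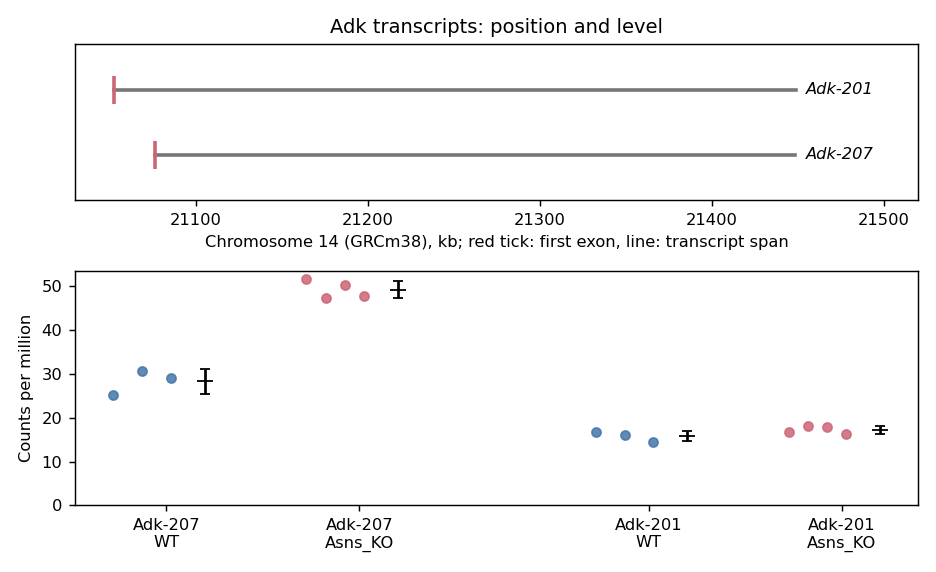
The upper panel places both Adk transcripts on chromosome 14 (kilobases, GRCm38), with the span as a line and the first exon as a red tick; the lower panel gives CPM per library as points, WT in blue and Asns_KO in red, with mean ± SD. Adk-207 lies between 25.1 and 30.6 CPM in WT and between 47.4 and 51.6 CPM in Asns_KO, while the groups overlap for Adk-201.

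Most other genes were bounded to modest changes. The 95% interval of the fold change lay within 1.5-fold in either direction for 9586 genes, or 78.6% of those tested. At an unadjusted p under 0.05 there were 790 genes, 445 higher and 345 lower, where chance gives about 610. Of the 35 splits of the 7 libraries into groups of these sizes, the real one included, 7 gave as many or more. The other splits had a median of 451 such genes and up to 1888. Chance is therefore not excluded for this count. The groups did not overlap in 912 genes, 7.48% of those tested, where chance gives 5.71%. DESeq2 called 47 genes, 28 higher and 19 lower, limma-voom called 4, the fourth being Arhgef1, and edgeR with no low-count filter called 10, 5 higher and 5 lower.

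**Figure D3:**
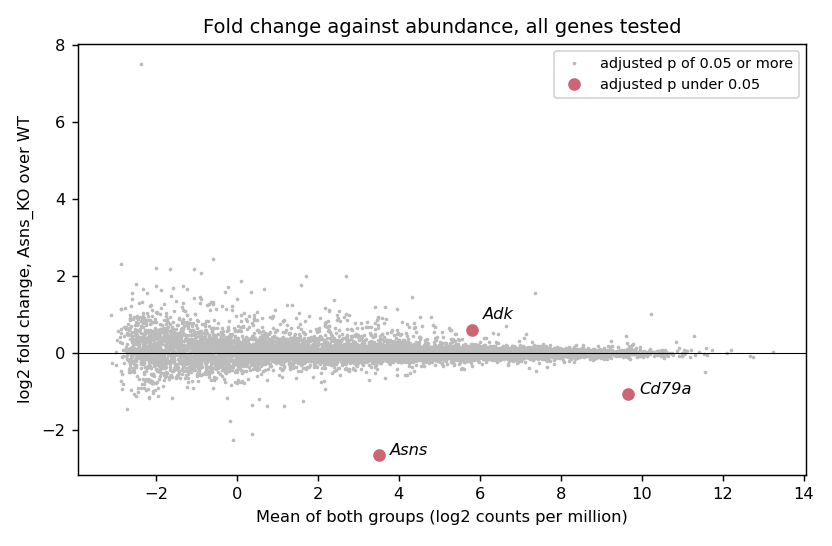
Each point is 1 of the 12197 genes tested, with the mean of both groups in log2 CPM on the horizontal axis and the log2 fold change of Asns_KO over WT on the vertical axis; the 3 genes with an adjusted p under 0.05 are red. Asns lies at -2.66, Cd79a at -1.07 and Adk at 0.60. The highest point, at 7.51, is the pseudogene Gm2436, which had no count in WT, so its fitted value depends on the prior count.

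The genes next in rank, named after their values were seen, did not pass the test with edgeR over the 12197 filtered genes. Among them were Ephx1, an epoxide hydrolase, with a log2 fold change of -0.57 (SE 0.07), and Fscn1, the actin-bundling protein fascin, with 0.66 (SE 0.10). The surface proteins Cd72, an inhibitory partner of the B cell receptor, and Fcmr, the Fc receptor for IgM, had -0.48 (SE 0.08) and -0.25 (SE 0.04). Their adjusted p-values lay between 0.0826 and 0.258 with edgeR, and DESeq2 called each of these 4. With no low-count filter edgeR called Ephx1 (adjusted p = 0.021), Fscn1 (0.021) and Cd72 (0.0391) as well. Arhgef1, a Rho exchange factor that starts 714 bases beyond the end of Cd79a on the same strand, had 0.24 (SE 0.03; edgeR adjusted p = 0.117), and was called by DESeq2 (adjusted p = 9.07e-08) and by limma-voom (0.0424).

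Of 33 gene lists fixed before the data were examined, 8 passed limma's camera test with a preset correlation of 0.01, 5 higher and 3 lower in Asns_KO. No list passed with a correlation estimated from the libraries, only the p53 targets passed fry, which tests each list on its own, and 17 of the 35 ways of splitting the 7 libraries into 3 and 4 gave as many called lists, so these lists are described as shifts of these libraries. In no list did a member pass edgeR's test over the 12197 filtered genes, although Egr3, of the light zone list, passed with no low-count filter (edgeR adjusted p = 0.0352). Of the 25 lists not called, the median of 15 turned sign with 1 library left out, and that of 24 turned sign or moved by over 1.5 times. Among the 782 members of any list, 84 had an unadjusted p under 0.05, DESeq2 called 8 and limma-voom called 0. The exact permutation test of the list scores gave a p of 0.0286 for the plasma cell list and the p53 targets. For the other lists called by camera its p ran from 0.114 to 0.257. As 0.0286 is the smallest p of that test, 2 lists at it among 33 could not pass after adjustment. Of the 35 splits, the real one included, 8 gave as many or more lists with an exact p under 0.05.

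Genes that respond to amino acid shortage through ATF4, the transcription factor of the amino acid response, were higher as a list, with a median log2 fold change of 0.07 over 33 members without Asns, 21 of them positive (camera adjusted p = 0.0131; adjusted p = 0.777 with an estimated correlation). None of the members passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. The proline synthesis enzyme Pycr1 had 0.52 (SE 0.14; 0.81 with an offset for effective length), Jdp2 0.18 (SE 0.08), Atf5 0.15 (SE 0.07) and Ddit4, an inhibitor of mTORC1, -0.15 (SE 0.07). Atf4 itself had -0.04 (SE 0.04), and its targets Trib3 and Ddit3, picked as textbook targets after their values were seen, had -0.16 (SE 0.25) and -0.05 (SE 0.12), both at 0.05 without WT replicate 3. The call was also lost without WT replicate 2 (adjusted p = 0.311), without Asns_KO replicate 3 (0.0537), without Asns_KO replicate 4 (0.188), with an offset for effective length (0.107) and with fry (0.548). The median fell to 0.03 without WT replicate 2 and to 0.02 without Asns_KO replicate 4.

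Other lists of amino acid and nucleotide metabolism did not pass camera. Enzymes that make or use asparagine, aspartate or glutamine had a median of 0.04 over 19 genes (adjusted p = 0.267), 12 of them positive, with Gfpt1 at 0.23 (SE 0.06), Ass1 at 0.54 (SE 0.20), Got1 at 0.14 (SE 0.05) and Gpt at -0.24 (SE 0.12). Without Asns_KO replicate 2, in which Ass1 stood at 37.7 CPM against 20 to 23 CPM in the other Asns_KO libraries, its value was 0.29. Amino acid transporters had a median of 0.06 (17 genes, camera adjusted p = 0.337), and the enzymes that charge tRNA in the cytosol 0.02 (20 genes, 0.308). Serine and one-carbon genes had 0.01 (17 genes, 0.64) and nucleotide synthesis 0.02 (30 genes, 0.267). In these 5 lists 4 genes in all had an unadjusted p under 0.05, and none passed when adjusted over the list alone. All 20 tRNA ligases and all 30 nucleotide synthesis genes had a 95% interval within 1.5-fold.

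Lists of energy metabolism did not pass camera over all 7 libraries. The 75 nuclear-encoded genes of the respiratory chain had a median of 0.01 (camera adjusted p = 0.808), and each of them had an interval within 1.5-fold. Without WT replicate 2 that list was called higher (median 0.04, camera adjusted p = 0.0204). The 13 mitochondrially encoded genes had 0.18 (0.312), where Asns_KO libraries ranged in score from -0.439 to 0.614 and WT libraries from -0.116 to 0.011. That list was called higher without Asns_KO replicate 1 (median 0.30, camera adjusted p = 0.000526) and had a median of -0.07 without Asns_KO replicate 3. The tricarboxylic acid cycle had 0.01 (23 genes, 0.308) and glycolysis 0.02 (23 genes, 0.38), with the glycolytic regulator Pfkfb4 at -0.40 (SE 0.13), Aldoc at -0.27 (SE 0.10) and Hk2 at 0.12 (SE 0.06). Hypoxia targets had 0.06 (17 genes, 0.356) and autophagy and lysosome genes 0.01 (27 genes, 0.856).

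Unfolded protein response genes were higher in Asns_KO as a list. Of 22 genes of the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum, 21 had a positive fold change and 9 an unadjusted p under 0.05, with a median of 0.14 (camera adjusted p = 8.47e-08; adjusted p = 0.67 with an estimated correlation). Examples were the chaperone Hsp90b1 at 0.44 (SE 0.14), Pdia4 at 0.48 (SE 0.15), Creld2 at 0.39 (SE 0.10) and Dnajc3 at 0.19 (SE 0.05). None of the 22 passed when adjusted over the list alone. The list score stood at 0.160 and 0.176 in Asns_KO replicates 2 and 4 and at -0.032 and -0.023 in replicates 1 and 3, beside -0.149 to -0.042 in WT. In the same Asns_KO replicates 2 and 4 the plasma cell score was 0.331 and 0.215, against 0.068 and 0.075 in replicates 1 and 3, and immunoglobulin constant regions took 1.113% and 1.098% of all counts, against 0.935% and 0.947%.

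Plasma cell genes had a median of 0.26 over 19 members, 15 of them positive (camera adjusted p = 9.21e-07; adjusted p = 0.665 with an estimated correlation), with 12 at an unadjusted p under 0.05. Adjusted over the list alone, 3 rose: Tent5c, which stabilises immunoglobulin RNA, at 0.48 (SE 0.09), the antibody joining chain Jchain at 0.26 (SE 0.07) and Prg2 at 2.00 (SE 0.54), the last of these at 11.7 CPM in Asns_KO replicate 2 and 2.72 to 3.44 CPM in the other Asns_KO libraries (log2 fold change 1.24 without replicate 2). Derl3, of the degradation machinery of the endoplasmic reticulum, had 0.35 (SE 0.11). The score was higher in all 4 Asns_KO libraries than in the 3 WT libraries (difference 0.40; exact permutation p = 0.0286, two-sided, and 0.471 after adjustment over the 33 lists). WT replicate 1 had the lowest score, -0.517, and the score difference was 0.258 without it. Without WT replicate 2 the median was 0.40. Immunoglobulin constant regions took 0.904% ± 0.0575 of all counts in WT and 1.02% ± 0.0954 in Asns_KO (SD, n = 3 and n = 4; exact permutation p = 0.171).

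Light zone genes, which mark germinal centre cells that receive antigen receptor and CD40 signals, were lower as a list, with a median of -0.08 over 34 members, 24 of them negative and 10 positive (camera adjusted p = 0.00219; adjusted p = 0.67 with an estimated correlation). Of these, 12 had an unadjusted p under 0.05. Adjusted over the list alone, 3 fell: the receptor-induced transcription factors Egr3 at -0.52 (SE 0.07) and Nr4a1 at -0.43 (SE 0.09), and the amino acid oxidase Il4i1 at -0.29 (SE 0.07). The costimulatory ligand Cd86 had -0.16 (SE 0.05). The call was lost without WT replicate 3 (adjusted p = 0.135) and, in a test added after the data were seen, without Egr1, Egr2, Egr3 and Nr4a1 (median -0.06, camera adjusted p = 0.086), and the median was -0.12 without WT replicate 1. Dark zone genes had a median of 0.00 (19 genes, camera adjusted p = 0.856). Germinal centre identity genes had a median of -0.03 (26 genes, 20 of them negative; camera adjusted p = 0.0672) with all 26 intervals within 1.5-fold. In that list Ms4a1 had -0.13 (SE 0.03), Pou2af1 0.12 (SE 0.04), Gcsam 0.13 (SE 0.05) and Lmo2 -0.12 (SE 0.05). Without Asns_KO replicate 4 the identity list was called lower (median -0.05, camera adjusted p = 0.0276).

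**Figure D4:**
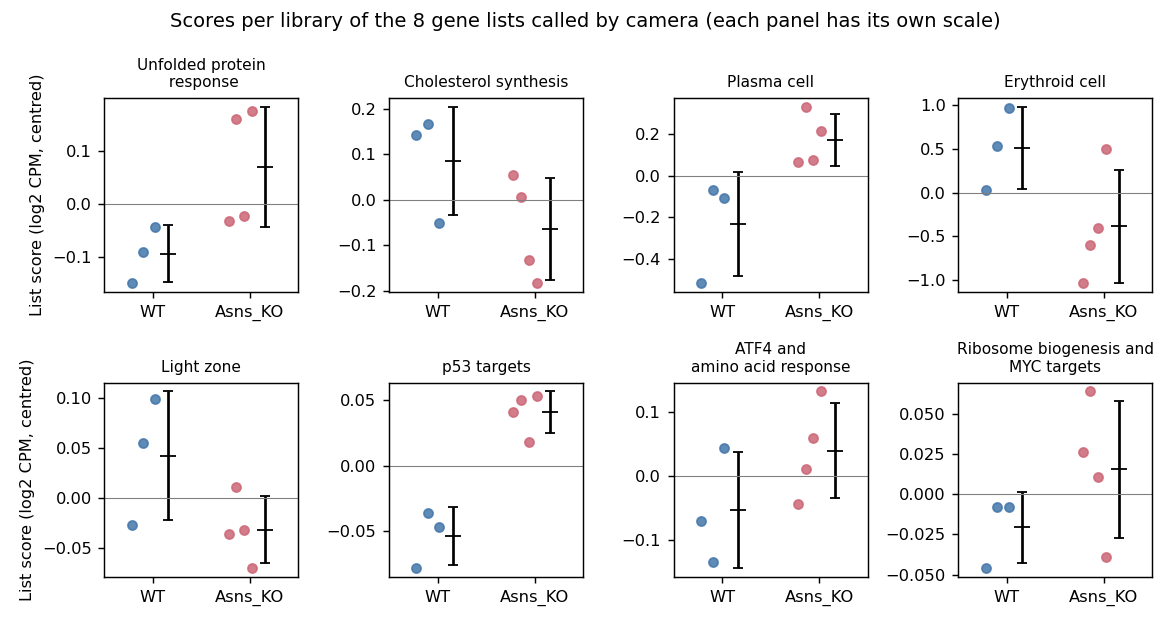
Each panel plots, for 1 of the 8 lists called by camera, the score per library (mean over members of log2 CPM centred on all 7 libraries) as points, WT in blue and Asns_KO in red, with mean ± SD; vertical scales differ between panels. The groups are apart without overlap for the plasma cell, p53 and unfolded protein response lists and overlap for the cholesterol, erythroid, light zone, ATF4 and ribosome lists.

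p53 targets were slightly higher, with a median of 0.06 over 26 members, 20 of them positive (camera adjusted p = 0.013; adjusted p = 0.318 with an estimated correlation). Their score was higher in all 4 Asns_KO libraries than in WT (difference 0.09; exact permutation p = 0.0286, two-sided, and 0.471 after adjustment). Trp53inp1 had 0.22 (SE 0.06), the proapoptotic gene Bbc3 0.25 (SE 0.08; 0.10 with an offset for effective length), Ccng1 0.11 (SE 0.04) and Cd80 0.39 (SE 0.17; 0.25 without WT replicate 1), with none past when adjusted over the list alone and 5 at an unadjusted p under 0.05. The median was 0.04 without Asns_KO replicate 2. Without WT replicate 1 the camera adjusted p was 0.0603, and with an offset for effective length 0.107. The BCL2 family had a median of -0.03 (16 genes, camera adjusted p = 0.808).

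Cholesterol synthesis genes were lower as a list, 22 of 23 with a negative fold change and a median of -0.16 (camera adjusted p = 3.03e-07; adjusted p = 0.695 with an estimated correlation). Dhcr7 had -0.17 (SE 0.04; -0.09 with an offset for effective length), Mvd -0.20 (SE 0.08), Hmgcs1 -0.21 (SE 0.08) and Lss -0.19 (SE 0.08; -0.12 with limma-voom). None passed when adjusted over the list alone, and 5 had an unadjusted p under 0.05. Ribosome biogenesis and MYC targets were higher, with a median of 0.04 over 33 genes, 28 of them positive (camera adjusted p = 0.0192; adjusted p = 0.777 with an estimated correlation), led by the spermidine synthase Srm at 0.12 (SE 0.04). That call was lost without WT replicate 1 (adjusted p = 0.235), without Asns_KO replicate 1 (0.0655), without Asns_KO replicate 2 (0.257) and with the effective length offset (0.107), and the median was 0.02 without WT replicate 1 or without Asns_KO replicate 2. All 33 intervals lay within 1.5-fold, and 1 gene had an unadjusted p under 0.05.

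Genes of the cell cycle passed no test over all 7 libraries. The 47 genes of DNA replication and S phase had a median of 0.00 (camera adjusted p = 0.856) and the 50 genes of mitosis and G2/M -0.02 (0.267), 36 of the latter with a negative fold change. The mitosis list was called lower by camera without WT replicate 3 (median -0.05, adjusted p = 0.000535) and without Asns_KO replicate 1 (-0.04, 0.0221). In both lists edgeR gave 0 genes an unadjusted p under 0.05, neither DESeq2 nor limma-voom called any, and all genes had an interval within 1.5-fold. Cytosolic ribosomal proteins had 0.01 (79 genes, 0.332), although many pseudogene copies make their counts less certain, and were called higher by camera without WT replicate 2 (0.04, adjusted p = 0.0293) and without Asns_KO replicate 4 (0.03, 0.00649). Replication-dependent histones, whose RNA mostly lacks a poly(A) tail, had 0.05 (15 genes, 0.584), and without WT replicate 2 were called higher by camera with 0.29 (adjusted p = 0.00164).

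Markers of other cells were measured beside these groups. Red cell genes were lower, with a median of -1.16 over 7 genes (camera adjusted p = 0.00177; adjusted p = 0.318 with an estimated correlation), at low levels: the globin gene Hbb-bt fell, adjusted over the list alone, from 15.4 CPM ± 1.63 (SD, n = 3) to 9.8 CPM ± 1.46 (SD, n = 4), a log2 fold change of -0.65 (SE 0.12), and Car2, Hba-a1 and Hbb-bs had -0.42 (SE 0.16), -1.38 (SE 0.67) and -1.24 (SE 0.68). Hbb-bs had -0.72 without WT replicate 2 and -2.08 without Asns_KO replicate 4, and Hba-a1 had -2.12 without the latter library. The red cell list kept its camera call without any 1 library, but its median was -0.72 without WT replicate 2 or without WT replicate 3, and -0.59 with no filter. Its score in Asns_KO replicate 4, 0.496, lay above that of WT replicate 1, 0.036. Hbb-bt did not follow Hbb-bs between libraries of 1 genotype. The pair stood at 17.2 and 1.17 CPM in WT replicate 1 and at 15.1 and 6.97 CPM in WT replicate 2. In Asns_KO replicates 1 and 4 it stood at 11 and 0.586 CPM and at 7.99 and 4.28 CPM. The globin gene Hbb-bh1, named after its values were seen, had -0.59 (SE 0.11). Globin genes have near-identical copies, so their split is uncertain, and the fall of Hbb-bt cannot be read as fewer red cells. T cell genes had a median of -0.17 (11 genes, camera adjusted p = 0.267) and myeloid genes 0.13 (7 genes, 0.267), a group in which Itgam rose adjusted over the list alone, from 1.22 to 2.64 CPM. The myeloid median was 0.05 without WT replicate 1 and 0.32 without Asns_KO replicate 1. The T cell list was called lower without WT replicate 1 (median -0.22, camera adjusted p = 0.0311) and had a median of 0.08 without WT replicate 2. Naive and memory B cell genes had 0.10 (24 genes, 0.364), with Sell at 0.87 (SE 0.25), Cr2 at -0.38 (SE 0.11), Fcer2a at -0.24 (SE 0.07) and Ighd at -0.48 (SE 0.15). That median was 0.03 without Asns_KO replicate 2 or without Asns_KO replicate 4, and 0.18 without Asns_KO replicate 1. Of these 24 genes, 15 were positive and 9 negative, and 11 had an unadjusted p under 0.05, as did 790 of all 12197 genes. None passed when adjusted over the list alone. Camera looks for a common direction, so members that move both ways can go uncalled. Marginal zone genes had -0.06 (12 genes, 0.253), and adjusted over the list alone S1pr3, at -0.41 (SE 0.08), and Cr2 fell. Without Asns_KO replicate 4 the marginal zone list was called lower (median -0.07, camera adjusted p = 0.0131).

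Signalling lists without a call over all 7 libraries were the interferon-stimulated genes (29 genes, median 0.01, camera adjusted p = 0.808), the immediate early genes (22 genes, -0.01, 0.856), in which Nr4a1 fell adjusted over the list alone, and NF-kB and MAPK feedback genes (14 genes, 0.00, 0.875). In the last of these the phosphatase Dusp2 fell when adjusted over the list alone, by 0.26 on the log2 scale (SE 0.06). The interferon list was called lower without WT replicate 2 (median -0.18, camera adjusted p = 0.0204) and without Asns_KO replicate 2 (-0.16, 0.0175). The interferon, immediate early, autophagy, feedback and dark zone lists differed in sign, or had a value of 0.00, between median, mean and test. Natural killer cell, stromal and sex chromosome lists had 1, 4 and 4 genes tested and were too short for camera.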

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

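The check for single libraries was set before the data were examined, although some genes it covered were chosen after their values were seen. It asked in the 4 Asns_KO libraries whether the highest or lowest stood apart from the other 3 by a gap above Dixon's 95% critical value, for 78 values, of which 7 did where chance gives about 3.9. The 3 WT libraries are too few for it.

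Prg2, a plasma cell and eosinophil granule gene, stood at 11.7 CPM in Asns_KO replicate 2 against 2.72 to 3.44 CPM in the other 3. Arhgef1 stood at 924 CPM in Asns_KO replicate 4 against 959 to 963 CPM. The score of interferon-stimulated genes was 0.373 in replicate 2 against -0.173 to -0.103, and that of autophagy and lysosome genes 0.0502 in the same library against -0.00296 to 0.00372. The score of immediate early genes was -0.131 in Asns_KO replicate 1 against 0.0543 to 0.0632, and that of the tRNA ligases -0.0158 against 0.0141 to 0.0176. Asns_KO replicate 1 also had the largest total, 64503516 estimated counts against 52947184 to 54535052.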

How the results depend on the processing

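The alternatives were planned before the data were examined, except the robust prior, the shortened lists and the leave-one-out of heavy chain shares. Over 849 alternative values of 64 results, which leave out the lists not called, 790 counted as unchanged and 0 as reversed. Unchanged meant within 1.5 times for a count, and the same direction and side of the threshold for a call. A gene or score not called in the main test only had to stay uncalled. With 1 library left out, score differences and heavy chain shares had to keep their sign and move by less than their pooled SD. Some of these moved by over 1.5 times, such as the plasma cell score difference from 0.402 to 0.258. Of the 25 lists not called, the median of 15 turned sign with 1 library left out, for example of T cell genes (-0.17, and 0.08 without WT replicate 2). The 3 genes called were among those called in all gene-level alternatives but 3: the effective length offset kept Asns and Cd79a, the 2-fold minimum kept 2 genes, with 0 higher, and leaving out Asns_KO replicate 3 kept Adk and Cd79a. DESeq2 called 47 genes (28 higher, 19 lower), no filter 10 (5 and 5), and limma-voom 2 higher. The cause was not tested. Leaving out 1 library gave 2 to 3 genes, 1 to 2 of them lower, and -2.89 to -2.36 for Asns. That value lost its call without Asns_KO replicate 3 (edgeR adjusted p = 0.0598).

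Lists called numbered 5 with the offset, 0 with an estimated correlation and 1, the p53 targets, with fry, which tests each list on its own. Leaving out 1 library gave 7 to 11, with lists gained as well as lost. Without Egr1, Egr2, Egr3 and Nr4a1 the light zone list had a median of -0.06 and a camera adjusted p of 0.086. With 1 library left out no exact score test can reach 0.05, so only score differences were computed, and each kept its sign.

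The replicate block changed 2 choices together, since Asns_KO replicate 4 is alone in its block and drops out of the contrast. With it 3 genes were called, 2 lower and 1 higher, and 10 lists. The ATF4 list was lost (camera adjusted p = 0.226), and the cytosolic ribosomal proteins (0.0174), germinal centre identity (0.0447) and marginal zone (0.0447) lists were gained. Leaving out Asns_KO replicate 4 with no block gave the same loss (0.188) and the same gains (0.00649, 0.0276 and 0.0131), so these moves cannot be put down to the block alone. Same-numbered libraries deviated from their group means with correlations of 0.005, 0.169 and -0.005, and not every library correlated best with its own number, so the numbers were not taken to pair libraries.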

Other observations

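The analyses of heavy chain genes, of other immediate early genes, of other light zone genes and of the gap between Arhgef1 and Cd79a were chosen after the values were seen. In antibody heavy chain RNA, shares of 4 isotypes did not overlap between the genotypes, although none passed after adjustment. Ighm made up 49.9% ± 6.52 of heavy chain constant region counts in WT and 31.4% ± 2.26 in Asns_KO (SD, n = 3 and n = 4; exact permutation p = 0.0286), and Ighd 0.343% ± 0.0914 and 0.218% ± 0.0167 (exact p = 0.0286). Ighg2b made up 11.1% ± 1.25 and 20.1% ± 3.43 (exact permutation p = 0.0286) and Ighg2c 1.17% ± 0.315 and 3.03% ± 0.794 (exact p = 0.0286). Ighg1, the most abundant switched isotype, stood at 29.4% ± 4.79 and 36.2% ± 6.87 (exact p = 0.229), and Ighg3, Ighe and Igha overlapped too. Adjusted over the 8 genes, the 4 smallest exact p-values became 0.0572. Each of the 4 stood at 0.0286, the smallest p the exact test can give with these libraries. With 4 of 8 genes at that limit no adjusted p under 0.05 was possible, so missing the threshold decides nothing here.

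Switched isotypes (IgG, IgA and IgE genes) together took 42.4%, 51.3% and 55.4% of these counts in the WT libraries and 70.3%, 65.8%, 70.2% and 67.1% in the Asns_KO libraries (exact permutation p = 0.0286). The rest of these counts lay on Ighm and Ighd, so the switched share restates the lower share of Ighm and is no separate result. Its exact p, unlike those of the single isotypes, was not adjusted. The difference in switched share stayed between 15 and 21.5 percentage points with any 1 library left out. Counts of Ighg2b and Ighg2c may be mixed in part because the genes are similar in sequence, but the share of Ighm does not rest on that split. Single genes did not pass the test over the 12197 filtered genes: edgeR gave Ighg2c a log2 fold change of 1.55 (adjusted p = 0.177), Ighg2b 1.01 (0.258) and Ighm -0.50 (0.585). With no low-count filter edgeR called Ighg2b and Ighg2c, and DESeq2 called all 3 (adjusted p = 0.00109 for Ighg2c, 0.00873 for Ighg2b and 0.00416 for Ighm).

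By splitting the libraries, chance cannot be excluded for either count of calls, but the splits weigh a count and not the genes in it. Among the 3 genes, Asns is the deleted gene and the Cd79a locus carries the cre. Cd79a stood at 513 to 536 CPM in Asns_KO and 1070 to 1130 CPM in WT. Asns stood at 2.31 to 3.88 CPM in Asns_KO and 13 to 27.3 CPM in WT. These values argue against chance for both genes. The real grouping called 3 genes, and 2 of the 35 splits of the 7 libraries into 3 and 4, the real one included, called as many; the other called 19 genes. It sets WT replicate 2 with Asns_KO replicates 1 and 2, which points to a structure of the libraries apart from genotype. For gene lists, the real grouping called 8 and 17 of 35 splits called as many, with up to 11 in another split.

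Egr3 and Nr4a1, which antigen receptor signals induce, were lower in all 4 Asns_KO libraries than in WT. Tissue handling would move immediate early genes together, but the 21 others had a median log2 fold change of 0.01 (95% bootstrap interval over genes -0.03 to 0.08). Egr1 among them nevertheless had -0.20 with no overlap between the groups. Such intervals resample genes and hold no spread between libraries. The score of the immediate early list, Nr4a1 included, ran from -0.131 to 0.063 in Asns_KO and from -0.109 to 0.087 in WT. A part played by handling is therefore not excluded. A smaller share of light zone cells stays open for part of the difference, since the 32 other light zone genes had a median of -0.07 (-0.10 to -0.04), 22 of them below 0, which is less than the -0.52 of Egr3. Another hypothesis that stays open is that less Cd79a, the receptor chain at 0.476 of its WT level, may lower these targets apart from Asns: the labels name no group with cre and intact Asns, and Cd79a varied by only 1.94% (coefficient of variation) over the Asns_KO libraries, so the effects of cre and of Asns loss cannot be told apart.

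Plasma cell genes may be higher because plasma cells were carried into the sort (whose gate on CD19, lower on plasma cells, and GL-7 would leave many of them out), because some germinal centre cells had begun to differentiate, or because of library yield. The share of all counts on immunoglobulin constant regions had a log2 ratio of 0.18 between the genotypes (95% interval -0.06 to 0.41), which neither shows nor excludes carried plasma cells, and it followed the list score over the 7 libraries (Spearman rho 0.89, permutation p = 0.0123, adjusted 0.0246 over the 2 relations computed; Pearson r 0.91, permutation p = 0.00179, adjusted 0.00358, and 0.95 without the 2 libraries farthest from the median share). Of the surface genes of plasma cells, Sdc1 had 0.51 (SE 0.23), or 0.24 without WT replicate 1. It stood at 4.69 to 10.3 CPM in WT and 9.7 to 13.2 CPM in Asns_KO. Tnfrsf17 had 0.22 (SE 0.48), or -0.17 without WT replicate 1, at only 0.142 to 0.685 CPM over all libraries. Slamf7 had -0.02 (SE 0.04) at 177 to 190 CPM, a level at which a few plasma cells may not show. These 3 genes therefore do not settle whether plasma cells were carried over. Total counts and the list score had a Spearman rho of -0.54 (permutation p = 0.236, also after adjustment) and a Pearson r of -0.19 (permutation p = 0.691, also after adjustment), or -0.39 without the 2 libraries farthest from the median total, so yield stays open too. A change within germinal centre cells was not tested, and none of these explanations was tested for the unfolded protein response list, whose score was also highest in Asns_KO replicates 2 and 4.

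Arhgef1, directly downstream of Cd79a, was higher in all 4 Asns_KO libraries than in WT. Shared reads are argued against by the 714 bases between the annotated genes and by the direction opposite to that of Cd79a. DNA of another strain brought in around the cre allele could change neighbours more often, but 5.83% of 120 other genes within 5 Mb had an unadjusted p under 0.05 (95% exact interval 2.38% to 11.6%), against 6.47% of 12075 genes elsewhere (one-sided Fisher's exact p = 0.664). The interval excludes shares above 11.6%, and so a share of 12.9%, double that elsewhere, but it does not exclude a smaller rise. A variant acting on Arhgef1 alone would go unseen, since Arhgef1 was left out, so strain DNA is not excluded. A local effect of the altered Cd79a locus on Arhgef1, such as transcription running on past Cd79a, is a possible explanation that was not tested.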
